A study of Mus musculus with 4 samples.

How the data were processed

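Dorsal root ganglion RNA of female mice was profiled in 4 libraries, which GEO's labels place in 1 group by titles carrying the word Pax. Per the labels' protocols, total RNA was isolated with TRIzol, depleted of ribosomal RNA with a RiboCop kit, and turned into libraries with a Lexogen QuantSeq 3′ kit, which reads a tag near the poly(A) tail of each transcript. Per the submitters' processing notes, FastQC 0.11.5, TopHat2 2.1.1, Bowtie2 2.2.9 and Cufflinks 2.2.1 were used, with the builds GRCm38.p4 and mm10 named. The settings, the annotation release, strand handling and any filter are not given in the sources used here.

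The authors deposited 1 table of 48431 genes with 4 value columns, named as TPM. Each column sums to 1000000. Within a column, 98.1% to 98.7% of the values above 0 lay within 0.05 of a whole multiple of 1 step, and that step was the same for every gene. The deposited values therefore act as CPM (reads scaled to a library total of 1000000), with no division by gene length left in them, and they are called CPM here. Dividing 1000000 by the step gave 6832828, 10839100, 11237298 and 10325999 reads for replicates 1 to 4. Because the remaining values are fractions of a read, no count model was applied. With 3 reads taken as the limit that a count of 0 allows, the limits were 0.439, 0.277, 0.267 and 0.291 CPM. There were 0 further columns of per-sample values. The columns were matched to the samples by Pac, F for female and the replicate number.

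The lists, pairs, thresholds and within-library tests were fixed before the data were examined. The alternatives that divide by exon length, remove ribosomal RNA or match random lists on transcript length were added afterwards, as were the tests of explanations that the closing section names as such. Since the kit reads a tag near the poly(A) tail, dividing by exon length may add a bias of its own. It is given only to show how far ratios between genes move. The design had assumed that the table was TPM with a length division, and multiplying by exon length, listed beforehand as another setting, was dropped once the values showed none. Detection meant at least 1 CPM in each of the 4 libraries. Log values are log2(CPM + 1), and the pseudocount of 1 understates ratios of low genes. Gene pairs (35) and list pairs (10) were compared within each library as differences of log2 values, with a two-sided exact sign-flip permutation test over the 4 libraries and Benjamini-Hochberg adjustment within each family. With 1 group, no test between groups was made. Spread between libraries was described by the number of genes with a mean of at least 10 CPM and an SD of at least 0.5 (log2). Lists were described by the SD of their mean deviation, ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. This percentile describes these libraries and is not a p-value.

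The named genes were the 10 with the highest mean outside mitochondrial and ribosomal protein genes, the 3 highest members of each of 42 lists, the members of the pairs, the 10 with the largest SD, and those that Dixon's rule picked out, 177 genes in all. Some of these genes, and 6 of the 35 gene pairs, are counted in the totals but not reported here by name. Levels of other genes (Il6, Tnf, Il1b, Sprr1a, Gpr151, C1qb, C1qc, mt-Co1, mt-Co2, mt-Co3, Rpl29 and Atp5s) were named after their values were seen. Symbols come from the table; 3 list symbols were matched through older names (Fam19a4, Fam19a1 and Scn2a1). Coordinates and gene types come from GENCODE M21 on GRCm38, to which 99.2% of the gene identifiers matched without their version. Tests on simulated counts at the real means and depths, with gene noise of SD 0.2 (natural log) added, recovered 5 of 5 lists given a shared deviation and called 0 of 32 others among 39 lists. In another simulation of the same kind 200 of 200 genes shifted by 1 (log2) passed the SD threshold, and 279 of 8180 unshifted genes did. The simulated noise was independent between genes and smaller than the real spread, where 39.6% of genes passed that threshold. These simulations therefore do not give the rate of false calls in the real libraries, where genes vary together. Alternatives covered the pseudocount, the detection and expression thresholds, rescaling, Spearman's correlation and leaving out each library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.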

Results

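The series concerns dorsal root ganglia, the clusters of sensory nerve cell bodies beside the spinal cord, in a study titled after neuropathy induced by paclitaxel, a microtubule-stabilising chemotherapy drug. Gene expression was measured in 4 RNA libraries of ganglia from female mice of a strain labelled SW. All 4 titles carry the word Pax and form 1 group, with replicates numbered 1 to 4. The treatment field of the same 4 samples describes saline given as a control, so the labels disagree on what these mice received, and nothing below rests on either reading. No library of a second group was analysed here. The comparisons are therefore between genes and gene lists within each library, and between the 4 libraries. Nothing in the labels says that the replicates came from separate animals, so their spread may be partly technical. The libraries held 6832828, 10839100, 11237298 and 10325999 counted reads in replicates 1, 2, 3 and 4, as derived from the value of a single read in each column. Levels are given as CPM, reads scaled to a library total of 1000000, with the SD over the 4 libraries (n = 4). Because the libraries sample the 3′ ends of transcripts and carry no molecular identifiers, intervals on counts cover counting error only.

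Ganglion transcripts of nerve cells and of myelinating glia were among the most abundant. Of 48431 listed genes, 12594 reached 1 CPM in each of the 4 libraries, and single libraries had between 13641 and 14525 genes at that level. Outside the mitochondrial and ribosomal protein genes, the highest means included Hsp90ab1, a heat shock chaperone (12478 CPM ± 4651), Malat1, a nuclear long non-coding RNA (9298 ± 2814), Chchd2 (5951 ± 2822), Ywhah (5928 ± 2786), Uchl1, a deubiquitinase abundant in neurons (5513 ± 3435), and Actb (4485 ± 1124). Mitochondrially encoded genes took 11.3% of the reads in replicate 1, 3.25% in replicate 2, 2.83% in replicate 3 and 6.43% in replicate 4, and the 16S and 12S ribosomal RNA genes mt-Rnr2 and mt-Rnr1 made up most of this. The 3 overlapping features AY036118, Rn18s-rs5 and Gm42418, at a ribosomal RNA locus on chromosome 17 (39846353 to 39848827, GRCm38), were listed at 0 in replicate 1. They took 3.76%, 6.21% and 9.09% of the reads in replicates 2, 3 and 4. Xist, the RNA of the inactive X chromosome, stood at 262 CPM ± 84.5.

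The first question was which sensory neuron classes were visible in the bulk tissue. All 15 general sensory neuron markers reached 1 CPM in every library, led by Uchl1, the neuronal β-tubulin Tubb3 (2359 CPM ± 678) and the intermediate filament peripherin, Prph (1329 ± 568). Peptidergic nociceptor markers were led by Calca, which encodes calcitonin gene-related peptide (310 ± 196), and Tac1, the substance P precursor (300 ± 98.9). Non-peptidergic markers were led by the neurturin receptor Gfra2 (206 ± 64.7). The markers of large myelinated neurons included neurofilament heavy chain, Nefh (1630 ± 491), and Pvalb (189 ± 47.6). Pvalb stood at 201, 190, 240 and 126 CPM in replicates 1 to 4. It ranked the libraries as the summed skeletal muscle genes below did, and its cell source was not tested. Trpm8, the menthol and cold channel, stood at 1.37 ± 0.373 CPM. Calca was 4.07-fold higher than Calcb (log2 ratio 2.02 ± 0.55, higher in 4 of 4 libraries). Calca and Tac1 could not be ordered (log2 ratio -0.17 ± 1.52, 2 libraries each way), and their ratio was -0.79 without replicate 3 and 0.84 after dividing by exon length. Prph and Nefh could not be ordered either (-0.37 ± 1.13, 2 each way; 0.63 after dividing by exon length). As lists, peptidergic markers averaged 0.78 ± 0.24 (log2) below those of myelinated mechanoreceptors and proprioceptors in 4 of 4 libraries. Against non-peptidergic markers they were higher in 3 of 4 libraries (0.44 ± 0.41), and the mean difference was -0.29 when only members with a mean of at least 1 CPM were kept.

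Among the lists of non-neuronal cells, the myelinating Schwann cell and general glial lists had the highest summed levels (13295 CPM ± 4464 and 3780 ± 552). All 12 myelinating Schwann cell markers were detected in every library, among them Mbp (1868 CPM ± 351) and Pmp22 (1549 ± 1021). All 7 satellite glia markers, the cells that wrap neuronal somata, were detected too, led by Apoe (378 ± 198), Fabp7 (206 ± 186) and Glul (163 ± 31.7). The Schwann list averaged 1.37 ± 0.27 (log2) above the satellite list in 4 of 4. Macrophage markers reached 1 CPM in all libraries for 10 of 14 genes, among them the complement gene C1qa (226 ± 130) and the mannose receptor Mrc1 (65.7 ± 29.1). None of 9 lymphocyte markers did. Cd3e, a T cell receptor subunit, had 0 reads in all 4 libraries, which allows up to 0.439 CPM in the shallowest library. The macrophage list averaged 2.96 ± 0.27 (log2) above the lymphocyte list, or 5.07 with a pseudocount of 0.1. Granulocyte genes S100a9 (124 ± 64.2) and Camp (46.3 ± 21.4) and the globin gene Hba-a1 (1372 ± 669) were present, the last sharing near-identical sequence with Hba-a2, so that reads could be split between them. Endothelial markers averaged 0.28 ± 0.18 (log2) above mural cell markers in 4 of 4 libraries, but -0.14 when only members with a mean of at least 1 CPM were kept.

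**Figure D1:**
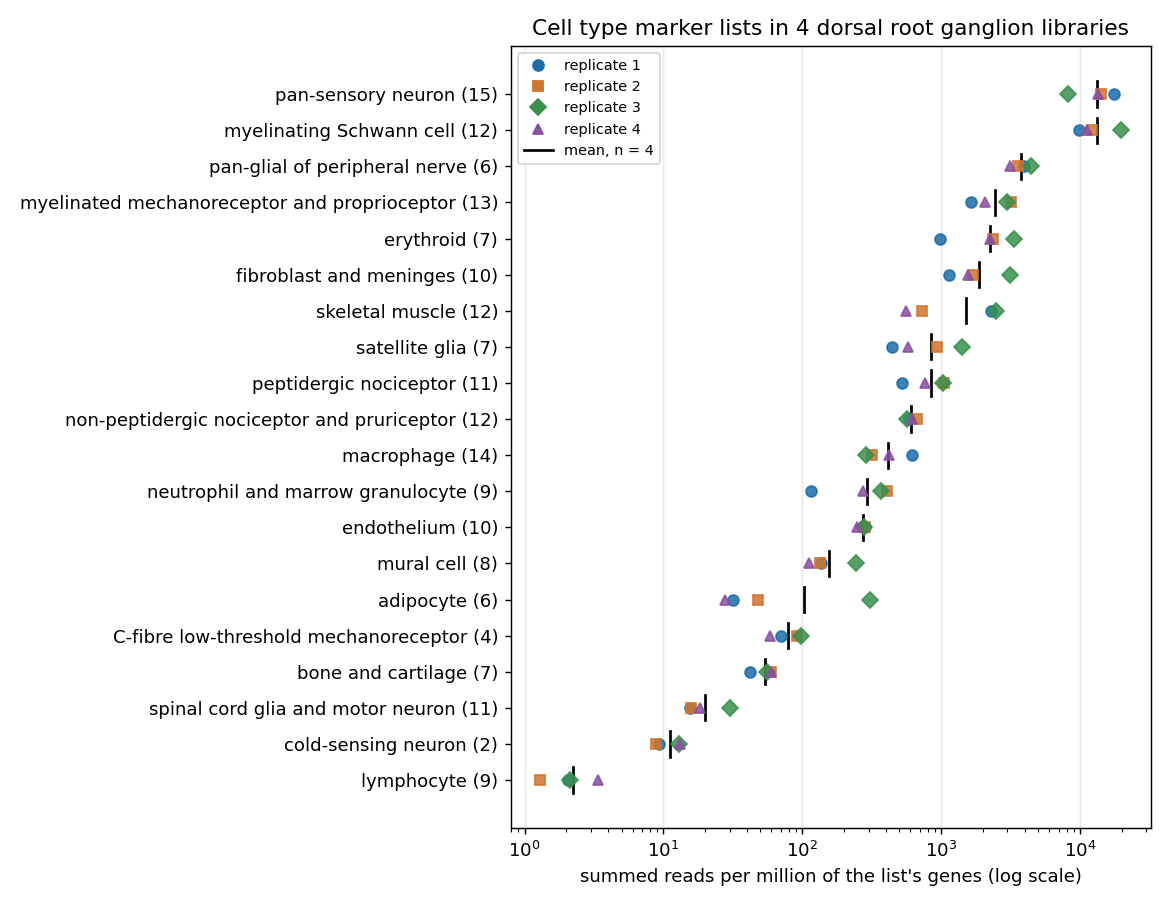
Summed CPM of each cell type marker list (log axis), with 1 symbol per library and a bar at the mean of the 4; the number of listed genes is in brackets. The myelinating Schwann cell and general sensory neuron lists lie highest, the lymphocyte list lies lowest, and the adipocyte list has 1 library, replicate 3, at 307 CPM.

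Markers of tissue that adjoins the ganglion were also read, and where these transcripts came from was not tested. All 12 skeletal muscle and all 10 fibroblast and meningeal genes were detected in every library. For spinal cord it was 6 of 11 genes, and for bone and cartilage 2 of 7. Skeletal muscle genes, among them the actin Acta1 (338 CPM ± 236) and the calcium pump Atp2a1 (204 ± 223), summed to 2269 CPM in replicate 1 and 2466 in replicate 3, against 728 in replicate 2 and 558 in replicate 4. General sensory neuron markers still averaged 2.04 ± 1.11 (log2) above the muscle list in 4 of 4 libraries. Spinal cord glia and motor neuron markers summed to 19.9 ± 6.9 CPM, and the neuron list averaged 6.98 ± 0.29 (log2) above them. Fibroblast and meningeal genes summed to 1881 ± 855 CPM, led by Col1a2 (595 ± 305) and Dcn (520 ± 236). Bone and cartilage genes summed to 54.1 ± 8.2 CPM, most of it from Comp (39.7 ± 7.33).

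Ion channel and analgesic receptor genes were compared next, as levels in the whole ganglion and not in any 1 class of neuron. All 12 sodium channel genes were detected in every library. Scn10a, encoding the tetrodotoxin-resistant channel Nav1.8 (686 CPM ± 208; chromosome 9, 119608456 to 119719322), was 2.74-fold above Scn11a (254 ± 90.8; log2 1.45 ± 0.52) in 4 of 4 libraries. Scn9a, encoding Nav1.7 (477 ± 122), was 5.16-fold above Scn8a (92.2 ± 24.99; log2 2.37 ± 0.75), while Scn9a and Scn10a were not ordered alike in all libraries (log2 -0.51 ± 0.53, Scn10a higher in 3 of 4). The mechanosensitive channel Piezo2 (545 ± 68.7; chromosome 18, 63010213 to 63387183) exceeded Piezo1 (1.87 ± 1.86) by 216-fold on the log2(CPM + 1) scale. Trpv1, the capsaicin receptor (18.3 ± 8.71), was 7.52-fold above Trpm8 and close to the irritant receptor Trpa1 (14.1 ± 4.98; log2 0.29 ± 0.25). The gabapentinoid target Cacna2d1 (209 ± 14.95) exceeded Cacna2d2 (69.3 ± 17.3) by 3.06-fold. The ATP-gated channel gene P2rx3 (26.6 ± 20.8) exceeded P2rx2 (0.317 ± 0.359) by 17.4-fold. The opioid receptor genes Oprm1 (0.365 ± 0.068) and Oprd1 (0.580 ± 0.273) both stayed under 1 CPM in every library, a few reads each, and could not be ordered (log2 -0.19 ± 0.31). Gabbr1, a GABA-B receptor subunit, led the analgesic receptor list (385 ± 87.3), and 7 of its 13 genes were detected in every library.

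Neurotrophic factor receptors and neuropeptides were compared in the same way. Ret, the GDNF family co-receptor, stood at 331 CPM ± 73.4, Ntrk2 at 90.2 ± 67.3 and Ntrk3 at 42.8 ± 18.5. The leukemia inhibitory factor receptor Lifr had the highest level of that list (537 ± 112). Among 16 neuropeptide genes, 9 were detected in every library, and the neuromedin B gene Nmb led them (673 ± 223). Galanin, Gal (103 ± 20.2), exceeded Npy (0.623 ± 0.725) by 67.1-fold on the log2(CPM + 1) scale. Mrgprd and Th, markers of separate C-fibre classes, could not be ordered (19.7 ± 17.3 and 20.5 ± 12.4 CPM; log2 -0.18 ± 0.51).

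Injury, stress and inflammation genes were then read as levels. Of 16 nerve injury genes, 11 were detected in every library, led by Cacna2d1, Jun (149 CPM ± 49.8) and the growth cone gene Gap43 (142 ± 65.5). Atf3, an injury-induced transcription factor (3.76 ± 0.89), was 30.5-fold below Jun (log2 of Jun over Atf3 4.93 ± 0.70). The injury genes Sprr1a (0.310 ± 0.281) and Gpr151 (0.045 ± 0.052) were near the floor. Of 16 inflammation genes, 6 were detected in every library, with Nfkbia (156 ± 38.6) and the chemokine Cxcl10 (12.1 ± 5.35) on top, while Il6, Tnf and Il1b each averaged under 1 CPM. The injury list averaged 2.09 ± 0.077 (log2) above the inflammation list in 4 of 4 libraries, and the difference was 3.12 with the median over members and 2.82 with a pseudocount of 0.1. The immediate early and heat shock list, which also tracks handling of tissue, had 11 of 14 members detected, led by Dusp1 (182 ± 84.6). Of the integrated stress and unfolded protein response genes, 15 of 16 were detected, led by the chaperone Hspa5 (2092 ± 348) and the transcription factor Atf4 (250 ± 93.6).

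Because the design text names ribosome profiling, the translation machinery was examined as a group. All 25 genes of the mTORC1 and Rag GTPase list were detected in every library, led by the Ragulator subunits Lamtor2 (271 CPM ± 54.4) and Lamtor1 (227 ± 98.3) and by Rraga, encoding RagA (176 ± 109; chromosome 4, 86575668 to 86577285). Rraga exceeded its relative Rragb (8.01 ± 2.63) by 17.4-fold (log2 4.12 ± 1.28), and Rragc (42.5 ± 9.34) exceeded Rragd (18.5 ± 3.91) by 2.23-fold (log2 1.16 ± 0.48), each in 4 of 4 libraries. Rictor, of mTORC2 (33.8 ± 6.54), was 3.18-fold above Rptor, of mTORC1 (10.1 ± 3.003). Of 25 translation initiation genes, 24 were detected in every library, led by Eif2s2 (508 ± 120), Eif4g2 (492 ± 84.3) and Eif4a2 (474 ± 94.8). The cap-binding protein genes Eif4e (107 ± 19.5) and Eif4e2 (105 ± 20.5) were not separable (log2 0.018 ± 0.55). The eIF4E repressor genes Eif4ebp2 and Eif4ebp1 (3.56 ± 1.997 and 3.01 ± 1.47) and the eIF4E kinase genes Mknk2 and Mknk1 (5.06 ± 3.02 and 4.16 ± 2.81) were not either. The mTORC1 list averaged 0.35 ± 0.11 (log2) below the initiation list in 4 of 4 libraries, and the difference was -1.04 with the median over members.

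Tubulin, the protein that paclitaxel binds, was represented by several isotypes. Of 29 tubulin and microtubule protein genes, 28 were detected in every library, led by Tuba1b (2965 CPM ± 1558), Map1b (2963 ± 706) and Tubb2b (2376 ± 496). Tubb3 was 9.25-fold above Tubb5 (323 ± 296; log2 3.21 ± 1.52) in 4 of 4 libraries, with a log2 ratio of 0.99 in replicate 3 and a mean of 3.95 without it, and higher than Tubb2a (1048 ± 609; log2 1.35 ± 1.16) in 3 of 4. Tubb4b (654 ± 528) was 37.9-fold above Tubb4a (12.7 ± 5.22). Tuba1a (1680 ± 1725) and Tuba1b could not be ordered (log2 -1.10 ± 1.03), and tubulin genes are similar enough that reads could be shared between copies. The drug efflux pump gene Abcb1a (55.7 ± 11.5) was 23.8-fold above Abcb1b (1.48 ± 0.93), and 8 of 17 drug transport and metabolism genes were detected in every library. Of 16 cell death and axon degeneration genes, 15 were detected, led by Mdm2 (326 ± 157), Map3k12 (79.7 ± 8.41) and Bax (45.9 ± 9.49). Nmnat2, an axon survival factor (28.5 ± 9.67), was 5.20-fold above Sarm1 (5.08 ± 3.36), its counterpart in axon degeneration.

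Over the 35 gene pairs, 22 had the same sign in all 4 libraries, and 20 of the 35 differed by more than 2 SD. Random signs would give the same sign in about 13% of pairs. That is no fair reference, as levels correlated at 0.857 or above between libraries, so genes at unlike levels tend to keep their order. The share among random gene pairs was not measured. Of the 10 list pairs, 8 had the same sign in all 4 libraries. The two-sided exact sign-flip permutation test over 4 libraries cannot go below p = 0.13 (rounded), which each same-sign pair reached (adjusted p = 0.199 over the 35 gene pairs), so no single pair can pass a threshold of 0.05. The ratios compare 3′ tags of different genes, so priming and mapping of each gene's 3′ end enter them. Even C1qa and C1qb, whose products join in 1 complex, stood at 226 and 2.40 CPM. The folds between genes are therefore ratios of tag counts, not of measured transcript numbers. Dividing by exon length moved the log2 ratio to -0.79 for Eif4ebp2 over Eif4ebp1, -1.18 for Scn9a over Scn10a, 4.04 for Tubb3 over Tubb5 and 6.78 for Gal over Npy, and leaving out replicate 3 moved it to 4.70 for P2rx3 over P2rx2. A pseudocount of 0.1 moved several log2 ratios of low genes by over 1.5 times in fold, to 8.51 for Piezo2 over Piezo1, 6.13 for P2rx3 over P2rx2, 7.61 for Gal over Npy, 5.35 for Abcb1a over Abcb1b and 3.54 for Trpv1 over Trpm8, and to 8.19 for sensory neuron over spinal cord markers. Without replicate 3 the mean levels of Tuba1a (820 CPM), Tubb4b (411), Tubb5 (179), Fabp7 (122), Ntrk2 (58.5), Mrgprd (11.3), Piezo1 (0.950), Npy (0.267) and P2rx2 (0.155) were lower by more than 1.5 times, as were those of Atp2a1 (93.7) and P2rx3 (16.7) without replicate 1.

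**Figure D2:**
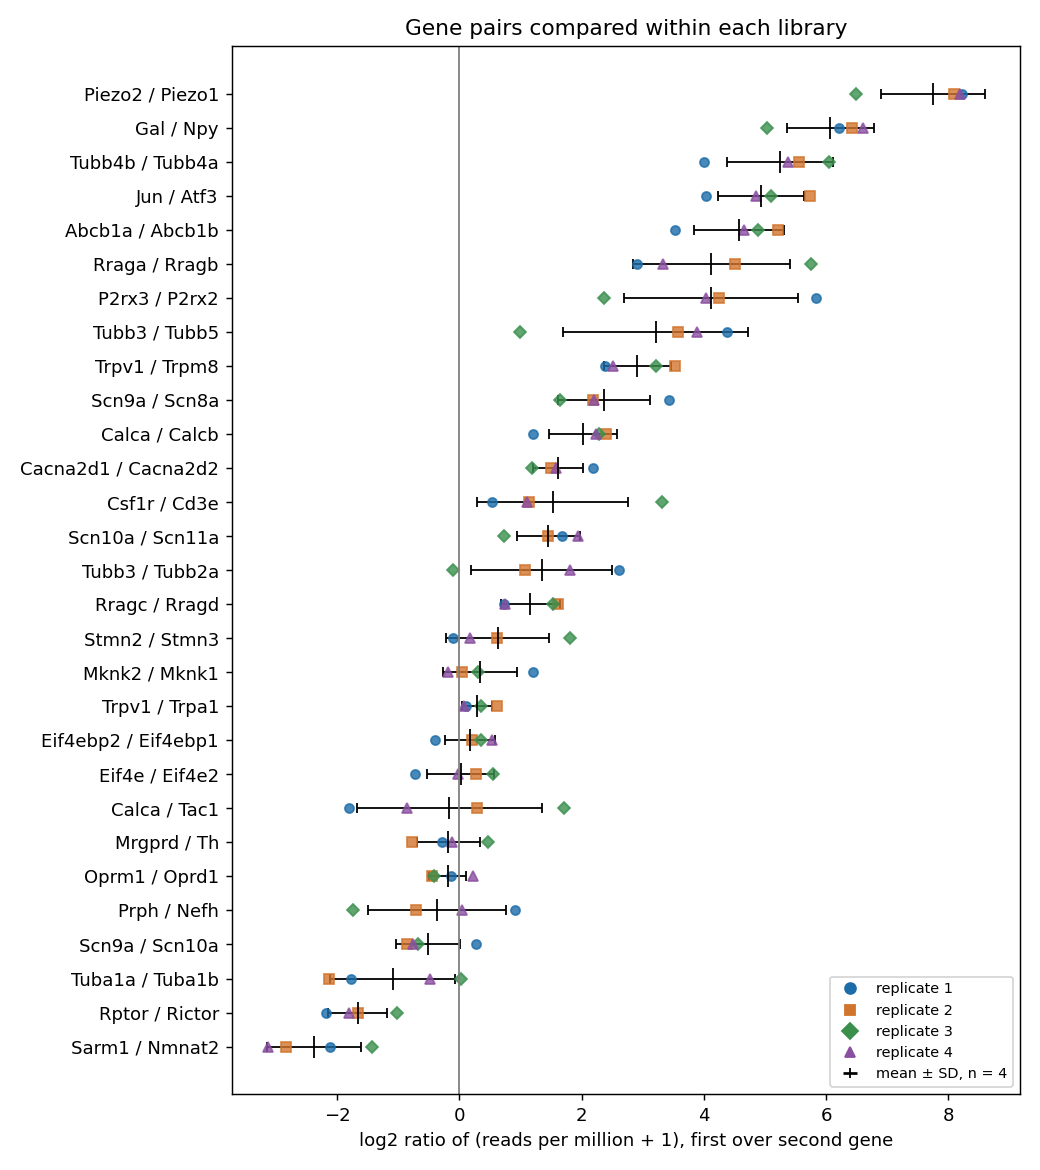
Log2 ratio of the first over the second gene within a library (CPM + 1) for 29 of the 35 pairs, with 1 symbol per library and the mean ± SD of the 4. Piezo2 over Piezo1 lies furthest to the right at 7.75 and Sarm1 over Nmnat2 furthest to the left at -2.38; pairs such as Calca over Tac1 straddle 0.

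The last comparison was between the 4 libraries, which differed in muscle, adipose and mitochondrial respiratory genes. Skeletal muscle genes were above their 4-library mean in replicates 1 and 3 (0.96 and 0.81, log2, relative to the median of all genes) and below it in replicates 2 and 4 (-0.76 and -0.99). Adipocyte genes stood at 1.72 in replicate 3, with Cfd at 208 CPM there against 18.1 to 34.0 CPM elsewhere, and Ucp1, the thermogenic gene of brown fat, at 63.4 CPM against 5.71 to 6.78 CPM. Nuclear oxidative phosphorylation genes stood at 0.73 in replicate 3 and -0.51 in replicate 1, and 63 of 77 members lay higher in replicate 3 than in replicate 1 relative to all genes. Myelinating Schwann cell genes were also at 0.77 in replicate 3. Nerve injury (SD 0.13, log2), mTORC1 and Rag (0.18) and stress response genes (0.18) stood at percentiles 25.9, 34.6 and 42.7 of random lists, and at 62.4, 54.6 and 38.4 after scaling to the same median.

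Of 39 lists with at least 3 measured members, 9 had an SD within the highest 2.5% of 10000 random lists of the same size matched on mean expression. These were the peptidergic nociceptor, satellite glia, myelinating Schwann cell, fibroblast, skeletal muscle, adipocyte, neurotrophic factor receptor, ribosomal protein and oxidative phosphorylation lists. After scaling all libraries to the same median, 3 remained, namely skeletal muscle, adipocyte and oxidative phosphorylation. Without replicate 3 the adipocyte (percentile 78.0), Schwann cell (80.5) and fibroblast (92.3) lists left this range, and the granulocyte (99.8) and erythroid (98.8) lists entered it. Without replicate 1 the peptidergic (94.4) and neurotrophic factor receptor (96.96) lists left it, and the tubulin list (98.5) entered it. The median of all genes shifted by -0.24, 0.12, 0.20 and -0.10 (log2) in replicates 1, 2, 3 and 4. Across the 14165 genes with a mean of at least 1 CPM, Pearson correlations between libraries ran from 0.857 (replicates 1 and 3) to 0.975 (replicates 2 and 4), with a median of 0.946. These are correlations across genes, which are not independent replicates. Of the 8427 genes with a mean of at least 10 CPM, 3340 (39.6%) had an SD of at least 0.5 (log2). The count was 2188 without replicate 3. Apart from the ribosomal RNA features, the most variable genes included Nme3 (0 to 56.2 CPM), Slc39a7 (2.57 to 81.4), Fam89a (18.7 to 455), Serping1 (2.195 to 62.7) and Ndufs8 (6.44 to 124).

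**Figure D3:**
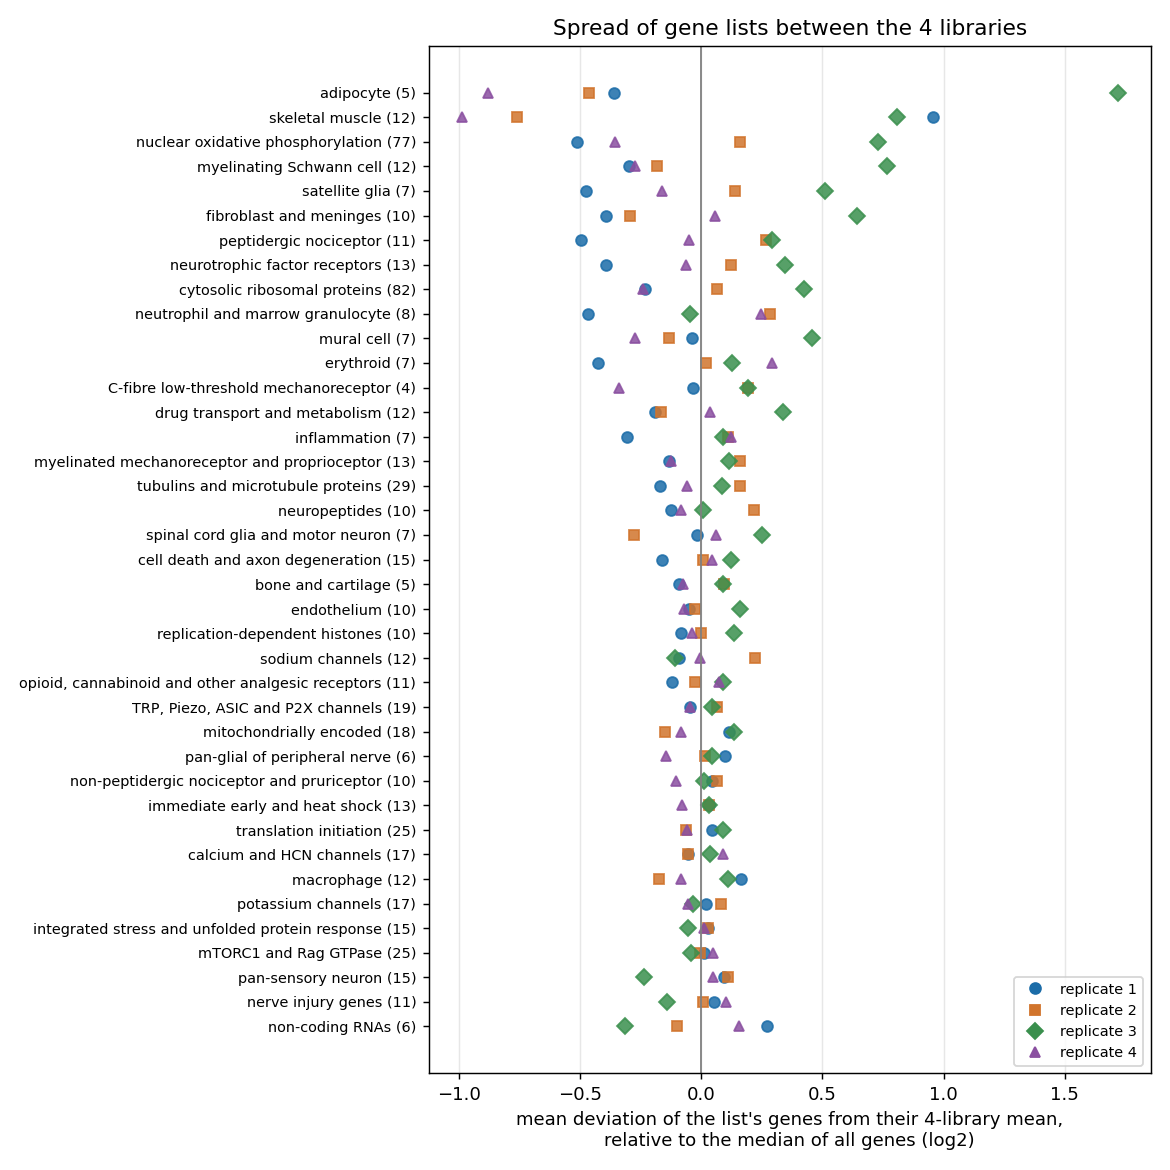
Mean deviation of each list's genes from their own 4-library mean, relative to the median of all genes in that library (log2), with 1 symbol per library; lists are ordered by the SD over libraries before that adjustment. The adipocyte list lies at 1.72 in replicate 3, and the skeletal muscle list lies near 0.96 and 0.81 in replicates 1 and 3 and below 0 in the others.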

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

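The tests of the neuron share, of male tissue and of both ribosomal RNA explanations were chosen after the results were seen, while those of GC content, transcript length and X-linked copies were set before. Dixon's rule, which compares a library's gap to its neighbour with the whole range, picked out 22 of 225 values. Its chance rate of about 5% holds for normally distributed values that were not chosen for their spread. Whether CPM values are normally distributed was not checked. The values tested included the 10 genes with the largest SD, which supplied 5 of the 22; among the other 215 values it picked out 17 (7.91%), a share not tested against chance, since genes and lists of 1 library vary together. Replicate 3 held the highest value of the complement regulator Serping1 (62.7 CPM), Nme3 (56.2), Gm10039 (38.2), the adipose genes Cfd (208) and Ucp1 (63.4), Flt1 (54.5), Pdgfrb (51.2), Csf1r (8.99) and Tuba1a (4257), and of the summed adipocyte list (307). Replicate 1 held the highest value of 2900060B14Rik (223 CPM), Atp2a1 (537), Tagln (50.8), Cd3d (1.17, from 8 reads) and Ddx3y (7.02), and the lowest of Slc39a7 (2.57). Replicate 2 was highest for Cxcl10 (20.1 CPM) and Kcnq3 (13.1). Replicate 4 was highest for Ms4a1 (2.52 CPM) and lowest for Fam19a4 (41.9), Hist1h1c (48.9) and the summed endothelium list (246, against 280 to 283 elsewhere).

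Replicates 1 and 3 lay at the ends of the first principal component (81.4% of the variance), and the SD of their log2 ratio was 1.22 over genes with a mean of at least 10 CPM. GC content of the last 500 nt had a Spearman rho of -0.0826 with that ratio across 8178 genes (bootstrap 95% interval -0.104 to -0.0615). The rho was under the bound of 0.1 set beforehand for no such bias, with an interval that reached just past it. Bootstrap intervals here resample genes, which vary together, so they may be too narrow and cover only replicates 1 and 3. Of 15 general sensory neuron markers 7 lay above and 5 below the median of all genes by more than 0.5 (log2), so 33.3% were on the minority side. By the criterion written for this test, that would have counted against a difference in neuron share. As 32.1% and 34.2% of all genes lay as far out, this decides nothing about the neuron share, which stays open. Transcript length stays open too, since its rho of 0.104 (0.0827 to 0.126) fell between the bounds of 0.1 and 0.3. A later, looser rule that asked only for an interval under 0.3 would have counted against length too and is not used. No biological explanation other than the neuron share was tested here.

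The overlapping ribosomal RNA features AY036118, Rn18s-rs5 and Gm42418 were at 0 in replicate 1 (3 of 3), against 21477, 15086 and 1070 CPM in replicate 2, and were the only genes at 0 there with at least 100 CPM in each other library. The test of more complete depletion assumed that it would lower mitochondrial ribosomal RNA as well, which was not checked. The share of mitochondrial ribosomal RNA was 4.82 percentage points higher in replicate 1 than in the highest other library (SD over the 4 libraries 3.99). This counts against more complete depletion only if that assumption holds. Whether the authors' filtering or counting of that library differed stays open: the 3 features overlap at 1 locus and are the observation itself. A second criterion, mitochondrial ribosomal RNA not lower in replicate 1, was met by the same 4.82 points, but a library filtered like the others could meet it too, and it was dropped as support after the result was seen. No biological explanation was tested.

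Ddx3y, a Y-linked gene, had 48 reads in replicate 1 and 1 read in each other library, although all mice are labelled female. Reads shared with the X-linked copy Ddx3x would keep their ratio, but Ddx3y made up 0.872% of the reads of both in replicate 1 (exact 95% interval 0.643 to 1.15) and at most 0.0679% by the upper bounds elsewhere. A small amount of male tissue or RNA in replicate 1 could neither be shown nor excluded. The first criterion asked for at least 3 of 4 Y-linked genes above each other library by exact intervals, and 1 of 4 was, which by itself would have counted against it; 3 of the 4 had at most 10 reads there, too few to exclude it. A criterion substituted after that result, the highest CPM in replicate 1, was met by 4 of 4 genes and is given as a value only. Together the 4 genes had 69, 3, 8 and 8 reads in replicates 1 to 4, most of those in replicate 1 from Ddx3y. Kdm5d had 7 reads in replicate 1 and also 7 in replicate 3. No criterion was set for the summed reads.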

How the results depend on the processing

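The alternatives dividing by exon length, removing ribosomal RNA and matching on transcript length were chosen after the data were seen. Replicate agreement was 0.903 at a mean of at least 10 CPM, and variable gene lists numbered 3 after scaling to the same median; the cause was not tested. Endothelium against mural cells was -0.14 with members of at least 1 CPM, a setting that left out 1 mural cell gene and no endothelial gene. Leaving out 1 replicate at a time, variable genes numbered 2188 (without replicate 3) to 4081, detected genes 12667 to 13072, list members 543 to 558, gene pairs 23 to 26, list pairs 8 to 10, variable lists 8 to 9 (not the same lists) and agreement 0.921 to 0.960. The counts of detected genes, list members and same-sign pairs require every library, so they cannot fall when 1 is left out. Those counts therefore say nothing about stability. Without replicate 3, 1975 of the 3340 variable genes were among the 2188. The median over members moved 9 of 10 list pairs by more than their SD, and the pseudocount of 0.1 moved 8 of 45 gene and list pairs. Dividing by exon length gave 27 gene pairs and 8 list pairs, moved 14 of 45 pairs, and gave 5.86 for Piezo2 over Piezo1, 0.95 for Cacna2d1 over Cacna2d2, -1.08 for Rptor over Rictor, 1.25 for neurons over muscle and -0.18 for peptidergic over myelinated neurons; length-matched random lists gave 11 variable lists. The planned multiplication by exon length was not run, since the values carry no length division. No paired analysis was possible because only 1 group was present, so replicate numbers pair no samples across groups; gene and list pairs were compared within libraries. Depth limits statements on genes near 3 reads, such as Oprm1 and Cd3e.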

Other observations

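The tests on the ribosomal protein and oxidative phosphorylation lists below were set before their results, after the uneven levels had been noticed. Genes of the same list or of the same complex differed widely in level. Ribosomal protein genes with a mean of at least 1 CPM ran from Rpl29 (4.49 CPM ± 4.50) to Rplp1 (4750 ± 2463), and oxidative phosphorylation genes from Atp5s (5.76 ± 2.91) to Atp5g3 (3212 ± 682). The complement genes C1qa, C1qb and C1qc stood at 226 ± 130, 2.40 ± 1.42 and 12.6 ± 3.07 CPM, and the cytochrome c oxidase genes mt-Co1, mt-Co2 and mt-Co3 at 155 ± 84.1, 0.827 ± 0.525 and 564 ± 548 CPM.

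Over 158 ribosomal protein and oxidative phosphorylation genes, those with an internal run of at least 8 A had a median level -0.12 (log2) apart from the others (bootstrap 95% interval -1.49 to 1.25), and transcript length had a Spearman rho of -0.245 with level (-0.384 to -0.0897). Of the 158 genes, 11 had such a run. Both intervals resample genes, which vary together, so they may be too narrow. The criterion set beforehand took a negative difference as evidence against the run of A, so by itself it would have counted against it. The wide interval was taken into account for the run of A only after its value was seen. With that interval, neither test decided the question.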
